A study of Mus musculus with 8 samples.

How the data were processed

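Poly(A) RNA was sequenced from 8 cultures of mouse bone marrow cells. Bone marrow was grown for 7 days either in GM-CSF at 20 ng/mL, which gives bone marrow-derived dendritic cells (BMDC), or in M-CSF at 10 ng/mL, which gives bone marrow-derived macrophages (BMDM). The donors were C57BL/6 mice with loxP-flanked Trpv2 alleles, without Cre (control) or with Cre recombinase expressed from the Lyz2 locus (knockout). Each cell type had 2 control and 2 knockout libraries. The series counts 2 mice of each genotype for each cell type; whether one mouse gave both a BMDC and a BMDM culture was not given in the sources used here. With 2 libraries per group, each gene's p-value rests on these few samples and on a spread estimated partly across genes.

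Per the labels' protocols, stranded mRNA libraries were made with a TruSeq kit and run on a NovaSeq instrument, reads were trimmed with cutadapt, and reads per gene were counted with HTSeq. Tool versions, the aligner and the strand setting of the counting were not given in the sources used here. The deposited counts are raw whole-number read counts per gene, in one table of 4 libraries for each cell type, per the file headers. The BMDC table lists 14755 genes and 14311 are in the BMDM table, with 13689 in both. Every listed gene has at least 1 read in its table. By gene ID, 99.8% of the matched genes are protein-coding in GENCODE M21. The authors also deposited FPKM values, which equal the counts scaled by the listed gene length and by the library total of the table. The authors' deposited comparison columns hold the mean signal of size factor-scaled counts, the ratio of knockout to control, its log2 value, and a p-value with its adjusted value; the tool behind them is not given in the sources used here. Coordinates are as deposited. The submitters' processing notes list GRCm38 and GRCm39, the protocol names GRCm38, and 2.26% of the genes start where GENCODE M21 on GRCm38 places them, so positions were not compared with that reference.

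Library totals were 16868675, 19463457, 17062351 and 17588322 counts in the BMDC (control 1, control 2, knockout 1, knockout 2) and 15964823, 15864433, 15790185 and 17176941 in the BMDM. A gene with no read in a library is bounded at 3 counts, which in BMDC control 1 is 0.178 CPM (counts relative to the library total). Such floors, and the 95% intervals given for ratios of reads, cover counting error only. No 2 libraries held the same values.

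Knockout and control were compared within each cell type by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr at a minimum count of 10, Benjamini-Hochberg adjustment and a threshold of 0.05. A joint fit of all 8 libraries over genes listed in both tables tested the difference between the knockout effects (BMDM minus BMDC) and compared BMDM with BMDC in the control libraries. Levels are TMM-scaled CPM. Fold changes are knockout over control, on the log2 scale with a standard error (SE). Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 where at least 5 members were tested, adjusted over the lists of a comparison. The same test with a correlation estimated from the data was an alternative. It rests on the residual degrees of freedom, 2 within a cell type and 4 in the joint fit, and so has little power. It passed 0 lists in every comparison, so failing it says little about a list. The preset correlation in turn takes list members as nearly independent. A list whose members move together in a single library can therefore pass at it, and passing does not show an effect shared by both libraries of a group. In all, 30 lists were fixed, of pathways, complexes and cell type markers, with 652 of their 702 entries matched to a listed gene. They included interferon-stimulated genes, MHC class II and antigen presentation, cell cycle, calcium entry, TRP channels, and the genes around Lyz2. The list called MHC class II for short also holds class I, antigen processing and costimulator genes.

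The design, lists and rule for named genes were fixed before the data were examined. The rule names Trpv2, Lyz2 and Lrmda, the last remembered from the published study. It adds the 8 largest changes in each direction among genes past the threshold with a mean of at least 1 CPM and no overlap between groups, leaving out predicted names. It adds the list members with the smallest p, up to 4 a list, and, where fewer than 3 genes pass in a direction, the 5 with the smallest p. For the cell type comparison it names list members and the 8 largest changes each way. Not every gene that the rule names is reported here.

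Alternatives fixed in advance were the DESeq2 1.42.0 test and size factors, limma-voom, no filter on low counts, a filter at 1 CPM, limma on log2(FPKM + 1) and log2(FPKM + 0.1), an absolute log2 fold change of at least 1, a replicate block, the joint fit, and leaving out each library. Where that left a group with 1 library, it was assumed to vary like the others. A list p-value of such a fit takes the list members as nearly independent, and describes that library rather than its group. Library quality weights, removal of a gene-length trend (lowess with a span of 0.3), a fit of the 4 control libraries only, and a crossed block were chosen after seeing the data. Each tool was tested on simulated counts with 200 changed genes, 2 libraries in each group and, for each gene, the same spread in all of them. No simulated library stood apart from the others. The changed genes were drawn from genes with higher counts than the filter requires, so the recoveries do not cover genes of low count. At the BMDM spread edgeR recovered 93 of 100 genes changed 2-fold and 100 of 100 changed 8-fold over 10918 genes. At the BMDC spread it recovered 0 of 100 at 2-fold and 77 of 100 at 8-fold over 11214 genes, where 6.10% of its calls and 25.2% of those of DESeq2 were false. Tables were handled with Python 3.11.15, pandas 2.3.3 and SciPy 1.17.1.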

Results

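The data are gene-level RNA-seq counts from BMDC and BMDM cultures of mice with loxP-flanked Trpv2, without Cre (control) or with Cre expressed from the Lyz2 locus (knockout). Lyz2 encodes lysozyme M, a bactericidal enzyme of myeloid cells, and its promoter drives Cre in macrophages, granulocytes and part of the dendritic cells. Trpv2 encodes a calcium-permeable cation channel of the TRP family. Each of the 4 groups held 2 libraries of 15790185 to 19463457 counts. The comparisons ask how the transcriptomes of knockout and control differ in each cell type, whether that differs between them, and how the control cultures differ. Cre in the Lyz2 locus goes with the loss of Trpv2 in each knockout library, so the comparisons cannot separate their effects.

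Trpv2 was low in each of the 4 knockout libraries, as the labels state. In the BMDM, it stood at 268 and 269 CPM in the controls and at 25.6 and 28.6 CPM in the knockouts, which is 10.1% of control. In the BMDC, it stood at 187 and 244 CPM in the controls and at 37.0 and 57.0 CPM in the knockouts, 21.8% of control. The gene (ENSMUSG00000018507) lies on the plus strand of chromosome 11, from 62465312 to 62491341 as deposited. The counts cover the whole gene, and which exons are flanked by loxP was not given in the sources used here. Lyz2 (ENSMUSG00000069516, chromosome 10, 117113236 to 117118226, minus strand) was lower still. It took 5.78% and 5.35% of all counts in the BMDM controls and 0.0249% and 0.0273% in the knockouts. In the BMDC it took 1.91% and 2.08% in the controls and 0.0120% and 0.0165% in the knockouts.

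**Figure D1:**
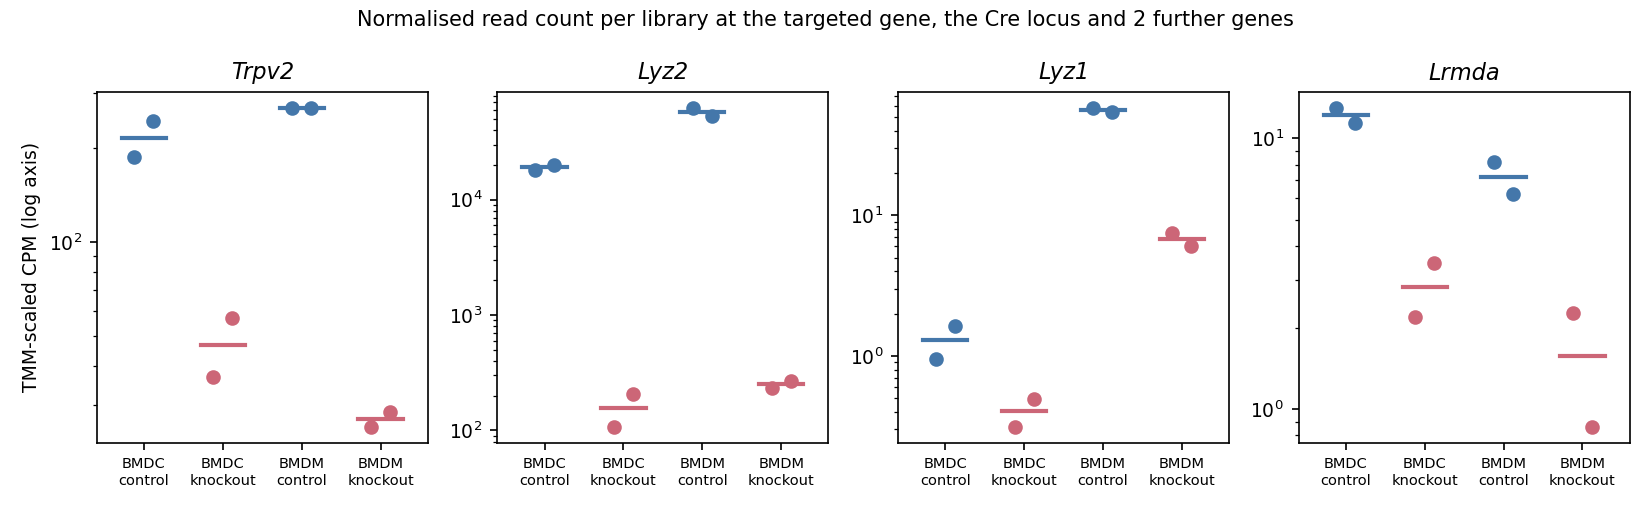
TMM-scaled CPM (log axis) of Trpv2, Lyz2, Lyz1 and Lrmda in each of the 8 libraries, with a point per library and a bar at the mean of the 2 libraries of a group. For each gene both knockout libraries lie below both controls of their cell type, for example at 25.6 and 28.6 against 268 and 269 for Trpv2 in the BMDM.

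In the BMDM, few genes differed between knockout and control. Besides Trpv2, the lysozyme genes fell, as did Lrmda, a gene of melanocyte differentiation, and the Y-linked translation factor gene Eif2s3y. The dynein light chain gene Dynlt1b, the neutrophil chemokine gene Cxcl1 and the scavenger receptor gene Colec12 rose. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 12 of 11024 genes passed, 5 higher and 7 lower, and 311 had an unadjusted p under 0.05, where 551 would by chance. All 12 had no overlap between groups, as did 26.7% of the tested genes, where chance gives 33.3%.

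Lyz2 fell by 7.85 on the log2 scale (SE 0.23, adjusted p = 4.1e-22), from 57879 ± 6410 to 252 ± 23.9 CPM (SD, n = 2 each, quasi-likelihood test of edgeR). Trpv2 fell by 3.31 (SE 0.17, adjusted p = 3.5e-15). Lyz1, the neighbouring paralog of Lyz2 on chromosome 10 (117123702 to 117128773), fell by 3.05 (SE 0.20, adjusted p = 2.1e-12), from 56.0 ± 2.71 to 6.77 ± 0.979 CPM; how reads shared by both lysozyme genes were counted is not given in the sources used here. Lrmda (chromosome 14, 22069780 to 23106153) fell by 2.20 (SE 0.37, adjusted p = 0.0022) to 21.7% of control, from 7.21 ± 1.39 to 1.57 ± 0.996 CPM. Eif2s3y fell to 46.1% of control (adjusted p = 0.0021), from 65.3 ± 2.92 to 30.1 ± 7.97 CPM. Ifi208, an interferon-inducible gene of the PYHIN family, had 29 and 22 reads in the controls and 0 and 1 in the knockouts, a ratio of 1.89% (95% interval 0.0470% to 11.03%, adjusted p = 0.0044). The remaining gene that fell had a predicted name.

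Dynlt1b rose 2.48-fold (log2 1.31, SE 0.19, adjusted p = 2.8e-04, edgeR), from 12.2 ± 0.906 to 30.1 ± 2.12 CPM. The cyclic nucleotide-binding domain gene Cnbd2 rose 2.46-fold (adjusted p = 0.024), and Cxcl1 2.37-fold (adjusted p = 0.035), from 18.0 and 7.11 to 24.4 and 34.8 CPM. Colec12 rose 1.73-fold (adjusted p = 0.042). Capn11, a calpain gene, had no read in either control and 19 and 24 reads in the knockouts, at least 6.90-fold higher against a floor of 3 counts per library (adjusted p = 0.012). Lyz2, Trpv2, Lyz1, Lrmda, Dynlt1b and the gene with the predicted name also passed without each of the 4 libraries in turn. Ifi208 was lost without control 1 or knockout 1, Capn11 without control 1 or 2, Cnbd2 without control 2 or knockout 2, Colec12 without control 1 or knockout 1, Cxcl1 without control 2, and Eif2s3y without knockout 2; the count was 34 without knockout 2. Colec12 and Cxcl1 were also lost with DESeq2 size factors, with the filter at 1 CPM and with limma on log2(FPKM + 1), and Colec12 with limma on log2(FPKM + 0.1). Cxcl1, Ifi208 and Capn11 were lost with DESeq2, and Ifi208, Cnbd2 and Eif2s3y with limma on log2(FPKM + 1). DESeq2 passed 9 genes and limma-voom 12, and the joint fit only Trpv2 and Lyz2.

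No gene list passed in the BMDM knockouts. The medians of interferon-stimulated genes (0.0033 on the log2 scale), MHC class II and antigen presentation (0.02), cell cycle genes (−0.0061) and calcium entry and store genes (0.01) lay near 0. Of the 49 interferon-stimulated, 22 MHC class II and antigen presentation, 34 cell cycle and 28 calcium genes tested, 0 passed over all genes. Adjusted over the list alone, 0 passed as well. Rsad2, an antiviral enzyme gene, stood at 118 and 58.3 CPM in the controls and 106 and 124 CPM in the knockouts. Slc8a1, a sodium-calcium exchanger gene, had 6.84 and 8.81 against 15.3 and 9.69 CPM. Of the 9 TRP channel genes tested (median −0.07), Trpv2 alone passed, over all genes and adjusted over the list alone. The endolysosomal channel gene Mcoln3 had a log2 fold change of 0.41 (SE 0.19) and Mcoln2 one of −0.16 (SE 0.16), neither past the threshold.

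Among 28 inflammatory cytokine and chemokine genes (median 0.14), Cxcl1 rose and 27 did not pass, with 2 higher adjusted over the list alone; Il1a had a log2 fold change of 1.01 (SE 0.23, adjusted p = 0.12 by edgeR), and passed without the low-count filter (adjusted p = 0.011), with limma on log2(FPKM + 0.1) (adjusted p = 0.040) and without control 1 (adjusted p = 0.0096). Of 26 phagocytosis and scavenger receptor genes Colec12 rose, with 2 higher adjusted over the list alone. Their median was −0.0086, their mean 0.09 and the test pointed up. Of 18 macrophage markers (median −0.03) Lyz2 fell, also adjusted over the list alone, and C1qa stood at 80.4% of control without passing. Of the 11 genes around Lyz2 on chromosome 10, Lyz1 fell, also adjusted over the list alone. Their median was 0.05, their mean −0.26 and the test pointed down, and Yeats4 (−0.22) and Frs2 (0.25) did not pass. The cell cycle test pointed up with a median and mean below 0.

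In all, 0 of 24 lists passed in the BMDM with camera at the preset correlation (6 at an unadjusted p under 0.05, smallest adjusted p = 0.058) and 0 with an estimated correlation. Without control 1, control 2, knockout 1 and knockout 2, in that order, 5, 1, 9 and 0 lists passed. The interferon-stimulated list was among them without control 1 (median 0.47), without control 2 (−0.28) and without knockout 1 (0.16). Its direction thus depended on the library left out. Its medians were 0.40 and −0.40 in the controls and −0.13 and 0.21 in the knockouts, relative to the control mean. Among the other lists that passed were cytokines without control 1 (0.74) or knockout 1 (0.24). MHC class II (0.13) and the genes around Lyz2 (−0.08) passed without knockout 1, and TRP channels without control 1 (−0.07) or knockout 1 (−0.12). The TRP list holds Trpv2 itself and the list around Lyz2 holds Lyz1. Neither was tested without that member, so these passes do not tell whether the other members fell.

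In the BMDC, Trpv2, Lyz2 and Lrmda were again low in both knockout libraries, and no gene passed the test. Lyz2 stood at 19032 ± 1471 CPM in the controls and 156 ± 68.9 in the knockouts (SD, n = 2 each), 0.820% of control. Its log2 fold change was −6.93 (SE 0.68, adjusted p = 0.54 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Trpv2 stood at 216 ± 40.7 and 47.0 ± 14.2 CPM, with a log2 fold change of −2.20 (SE 0.42, adjusted p = 0.97 by edgeR). Lrmda stood at 12.2 ± 1.08 and 2.82 ± 0.894 CPM, 23.1% of control, with one of −2.11 (SE 0.48, adjusted p = 0.97 by edgeR). Lyz2 passed edgeR's test without control 1 (adjusted p = 1.0e-08), control 2 (adjusted p = 1.5e-07) or knockout 1 (adjusted p = 0.011), and Trpv2 (log2 −1.93, adjusted p = 0.015) and Lrmda (log2 −1.83, adjusted p = 0.023) without knockout 1.

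With the smallest p among higher genes, none past the threshold (each adjusted p = 0.97 by edgeR), were Ms4a14, the membrane dipeptidase gene Dpep3, the inhibitory lectin receptor gene Clec12a, the dendritic cell chemokine gene Ccl17 and the ribonuclease gene Rnase4. Ms4a14 stood at 7.84 ± 2.34 CPM in the controls and 38.8 ± 16.9 in the knockouts, and Clec12a at 38.5 ± 3.72 and 107 ± 24.5. Ccl17 stood at 4.14 ± 2.43 and 27.3 ± 16.8 CPM. With DESeq2, Ms4a14 and Ccl17 passed (each adjusted p = 0.046). Among the lower genes with the smallest p, beside Trpv2, Lyz2 and Lrmda, was Fam167a (log2 −1.32, SE 0.41).

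By edgeR, 0 of 11357 BMDC genes passed, with 128 at an unadjusted p under 0.05 (116 higher and 12 lower), where 568 would by chance. DESeq2 passed 6 genes (3 higher and 3 lower), limma-voom 0, and 25.2% of genes had no overlap between groups, where chance gives 33.3%. Knockout 2 stood apart from the other BMDC libraries. Its Spearman correlations with them over genes were 0.940 to 0.945, while the others correlated with each other at 0.980 to 0.984. Its level also followed gene length, from a median log2 deviation of 0.77 in the quintile of shortest genes to −0.72 in the quintile of longest. The biological coefficient of variation was 0.406 in the BMDC and 0.134 in the BMDM. Without knockout 1, 3215 genes passed (1486 higher and 1729 lower), without control 1 there were 5 and without control 2 there were 16, and without knockout 2 there were 0.

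**Figure D2:**
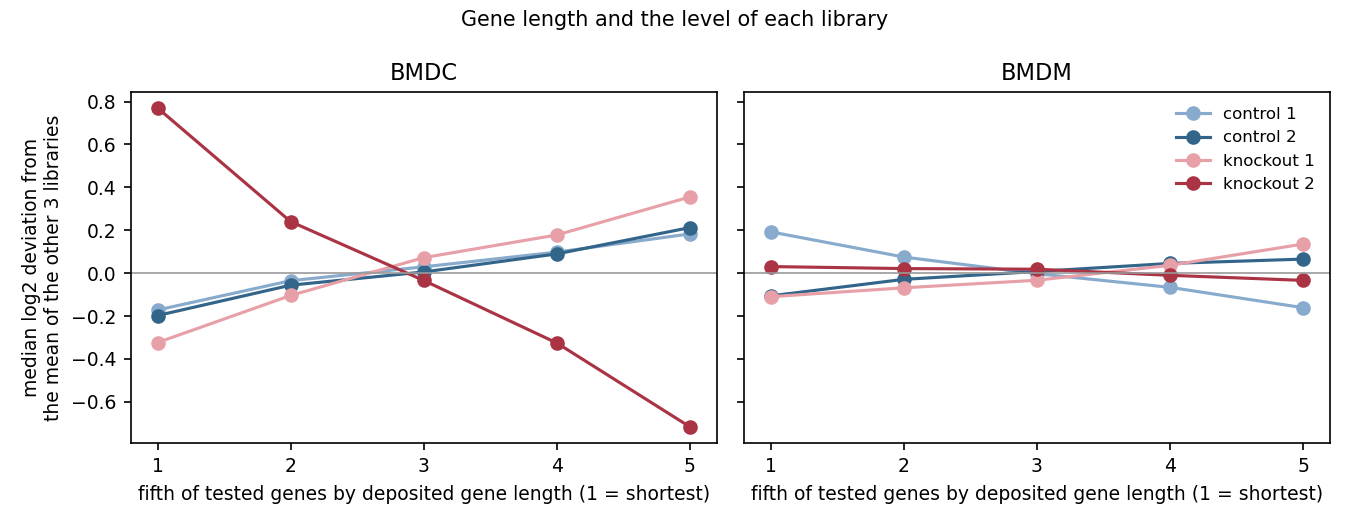
Median log2 deviation of each library from the mean of the other 3 of its cell type, in quintiles of the tested genes by deposited gene length, with a line per library. BMDC knockout 2 goes from 0.77 for the shortest genes to −0.72 for the longest, and the BMDM libraries stay between −0.16 and 0.19.

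Of the 27 lists tested in the BMDC, 10 passed, 8 higher and 2 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.69). No list had a member past the threshold over all genes. Adjusted over the list alone only Trpv2 (TRP channels) and Lyz2 (macrophage markers) passed. Without knockout 1 and knockout 2, 3 and 5 lists passed. The other 17 lists had medians from −0.30 to 0.72, among them calcium entry and store genes (0.02 over 28 genes, adjusted p = 0.92) and TRP channel genes (0.10 over 10 genes, adjusted p = 0.52). The mean of the TRP channels was −0.17 and their test pointed down. In 3 of the 10 passing lists the knockout libraries went opposite ways from the control mean.

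Interferon-stimulated genes, the antiviral effector genes induced by type I interferon, rose in the BMDC knockouts with a median of 2.10 on the log2 scale over 49 genes (adjusted p = 1.5e-04 by camera, adjusted p = 0.71 with an estimated correlation). The rise was that of knockout 2 alone. The list's medians relative to the control mean were 0.21 and −0.21 in the controls, −0.90 in knockout 1 and 3.06 in knockout 2. Ifi27l2a stood at 8.32 and 8.36 CPM in the controls, 4.23 in knockout 1 and 441 in knockout 2. Ifi44 stood at 1.28, 1.34, 0.679 and 57.5 CPM and Ifi205 at 2.29, 0.989, 1.10 and 72.0 CPM in the same order. Without knockout 2 the median of the list was −0.95, and without knockout 1 it was 2.99. Each of these fits holds a single knockout library and describes that library, not the genotype.

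MHC class II and antigen presentation genes rose with a median of 0.89 over 23 genes (adjusted p = 1.3e-05 by camera, adjusted p = 0.69 with an estimated correlation). Their medians were 0.02, −0.02, −0.11 and 1.43 in controls 1 and 2 and knockouts 1 and 2. The class II chain gene H2-Eb1 stood at 22.5 and 42.2 CPM in the controls and 51.3 and 102 in the knockouts, and the costimulator gene Cd86 at 47.1 and 59.2 against 76.8 and 121. Without knockout 2 the list median was −0.12 (adjusted p = 0.41) and without knockout 1 it was 1.41. Dendritic cell markers rose with a median of 0.94 over 15 genes (adjusted p = 6.5e-04, adjusted p = 0.69 with an estimated correlation), at −0.24, 0.24, 0.58 and 1.43 in the libraries, did not pass without knockout 1 (0.93, adjusted p = 0.15), and had a median of 0.50 without knockout 2. The chemokine receptor gene Ccr7 stood at 2.57 and 1.43 against 5.12 and 10.3 CPM and the integrin gene Itgax at 64.4 and 72.9 against 118 and 204.

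Cell cycle genes rose with a median of 1.02 over 35 genes (adjusted p = 7.4e-10, adjusted p = 0.69 with an estimated correlation), here more in knockout 1 (1.55) than in knockout 2 (0.55), with −0.42 and 0.42 in the controls. The replication licensing gene Cdc6 stood at 1.12 and 1.34 against 4.54 and 3.25 CPM and the survivin gene Birc5 at 0.391 and 1.88 against 7.15 and 4.30. Without knockout 1 the median was 0.37 (adjusted p = 0.29), and without control 2 it was 1.80 and without control 1 it was 0.51. Phagocytosis and scavenger receptor genes rose (0.31 over 26 genes, adjusted p = 0.016, adjusted p = 0.69 with an estimated correlation), with the Fc receptor gene Fcgr1 at 67.6 and 132 against 101 and 1575 CPM. That list did not pass without control 1 (0.29, adjusted p = 0.37), knockout 1 (0.38, adjusted p = 0.054) or knockout 2 (−0.00081, adjusted p = 0.57), nor with the gene-length trend removed (0.27, adjusted p = 0.073), and its median was 0.58 without control 2.

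Markers of other cells moved as well, each adjusted p = 0.69 with an estimated correlation. B and plasma cell markers rose with a median of 2.31 over 5 genes of low count (adjusted p = 0.0041), with Cd79a at 0.391 and 0.791 CPM in the controls, 0.574 in knockout 1 and 12.8 in knockout 2, and the median was −0.05 without knockout 2 (adjusted p = 0.77) and 3.48 without control 2. Mast cell, basophil and eosinophil markers rose with a median of 0.90 over 8 genes (adjusted p = 0.0052), with Hdc at 6.36 and 1.68 against 3.60 and 17.9 CPM. They passed without control 2 (4.60) and not without control 1 (−0.02), knockout 1 (1.27) or knockout 2 (−0.16). Mitochondrially encoded transcripts, a sign of RNA quality, rose with a median of 0.38 over 11 genes (adjusted p = 0.019), with mt-Nd6 at 130 and 258 against 256 and 650 CPM. Their share of all counts did not rise: it was 1.04% and 2.04% in the controls and 1.78% and 1.41% in the knockouts, within the range of the controls. The list of these transcripts passed without control 2 (1.15) and not without control 1 (−0.10), knockout 1 (0.75) or knockout 2 (0.15), nor with the gene-length trend removed (−0.12).

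Heat shock and culture stress genes fell with a median of −0.32 over 13 genes (adjusted p = 0.019, adjusted p = 0.69 with an estimated correlation), at −0.34 and −0.31 in the knockouts. The members with the smallest p were oxidative stress response genes: Nqo1 stood at 21.2 and 18.1 against 10.6 and 10.4 CPM, Gclm at 192 and 242 against 145 and 83.8, and Txnrd1 at 357 and 401 against 255 and 110. The list did not pass without control 2 (−0.27, adjusted p = 0.13) or knockout 1 (−0.35, adjusted p = 0.33). The genes around Lyz2 fell with a median of −0.27 over 11 genes (adjusted p = 0.019, adjusted p = 0.69 with an estimated correlation), at 0.04 in knockout 1 and −0.61 in knockout 2. Lyz1, at 17 and 33 reads in the controls, had 6 and 7 in the knockouts. That list did not pass without control 1 (−0.21), control 2 (−0.34), knockout 1 (−0.65) or knockout 2 (0.02).

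**Figure D3:**
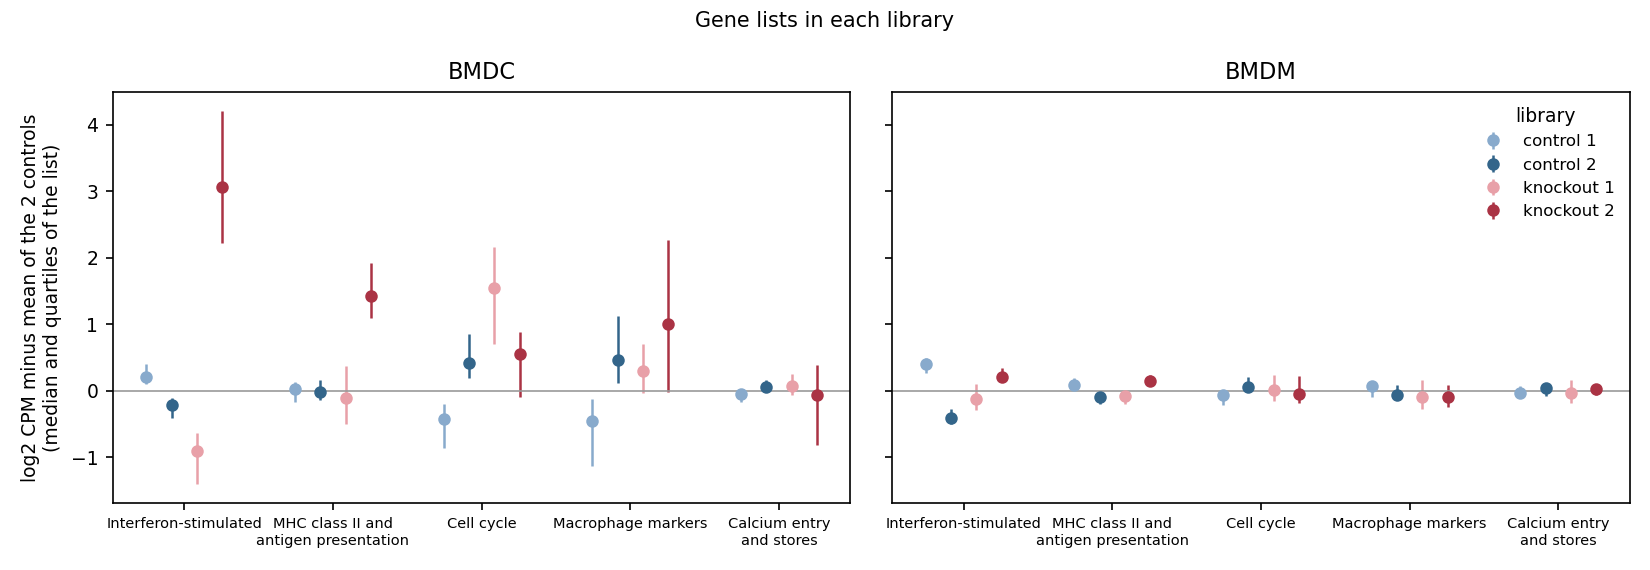
Median and quartiles of log2 CPM minus the mean of the 2 controls over the members of 5 gene lists, for each BMDC and BMDM library. Interferon-stimulated genes stand at 3.06 in BMDC knockout 2 and −0.90 in BMDC knockout 1, and the medians of calcium entry genes lie near 0 in every library.

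No gene was called in both cell types with edgeR, since none was called in the BMDC. With DESeq2 3 genes were called in both in the same direction, against 0.0022 for independent lists among the 10712 genes tested in both. Trpv2 and Lyz2, the genes altered by the knockout design, were among them, so this overlap was partly fixed in advance. Of the 12 genes called in the BMDM, 10 were tested in the BMDC. There 8, Trpv2 and Lyz2 among them, had the same direction (exact two-sided binomial p = 0.11). Adjusted over these genes alone in the BMDC by edgeR, 5 passed: Lyz2 (adjusted p = 4.7e-04), Trpv2 and the gene with the predicted name (adjusted p = 0.0059), Lrmda (adjusted p = 0.010) and Cnbd2 (adjusted p = 0.046). Cxcl1 (−1.03) and Colec12 (−0.18) had the opposite sign in the BMDC.

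The knockout effects of Trpv2, Lyz2 and Lrmda were not shown to differ between the cell types. The BMDM minus BMDC difference was −1.11 (SE 0.39) for Trpv2, −0.92 (SE 0.54) for Lyz2 and −0.08 (SE 0.67) for Lrmda, with adjusted p of 0.84, 0.84 and 0.97 by edgeR. Of 11671 genes 0 passed with edgeR and 0 with DESeq2, and 225 had an unadjusted p under 0.05 (53 higher and 172 lower), where 584 would by chance. Without BMDC knockout 1, 3733 genes passed, among them Trpv2 (−1.39) and Lyz2 (−1.31). Of 28 lists, 8 passed, 7 of them lower in the BMDM, and 0 with an estimated correlation (smallest adjusted p = 0.67). The number was 4, 2 and 5 without BMDC control 1, knockout 1 and knockout 2, and 4 without each of BMDM control 1, control 2 and knockout 2.

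Control BMDM and BMDC differed in many genes. With camera at the preset correlation macrophage markers were higher in the BMDM and neutrophil, monocyte, dendritic cell and inflammatory genes higher in the BMDC, and none of these lists passed with an estimated correlation (adjusted p from 0.28 to 0.48). Cell type and growth factor go together in this comparison. With edgeR, 1138 of 11671 genes passed, 545 higher and 593 lower in the BMDM, 3351 had an unadjusted p under 0.05, and 74.0% had no overlap between groups, where chance gives 33.3%. Of the named genes, Slc13a3, a dicarboxylate transporter gene, had the largest rise in the BMDM, at 948 ± 156 CPM against 0.260 ± 0.0920 (SD, n = 2). Fcrl5 stood at 18.3 against 0.0271 CPM and the Fc receptor-like gene Fcrls at 589.9 against 1.72. In the BMDC controls Fcrls stood at 0.217 and 3.21 CPM. Over the fits without 1 library its log2 difference ranged from 7.53 to 11.4, and that of Fcrl5 from 8.23 to 11.3. Pgbd5, Cd209g, Slc9b2, the folate receptor gene Folr2 and Scgb1a1 had no read in either BMDC control and from 1.57 to 6.17 CPM on average in the BMDM.

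On the BMDC side, Cyp1b1, the potassium channel gene Kcnn3, Ccn3, Csta2 and the collagen gene Col5a1 had no read in either BMDM control and from 8.04 to 26.8 CPM on average in the BMDC. The neutrophil chemokine gene Cxcl5 stood at 241 CPM in the BMDC against 0.0648 in the BMDM. The fibronectin gene Fn1 stood at 224 against 0.0993 and the arginase gene Arg1 at 453 against 0.227. The BMDC controls were uneven, at 123 and 783 CPM for Arg1, 111 and 371 for Cxcl5 and 126 and 322 for Fn1. Over the fits without 1 library the log2 difference of Arg1 ranged from −15.9 to −8.99. Of the 34 genes named by the rule here, 13 were lost in at least 1 of the 8 fits without 1 library, each of them without at least 1 of the BMDM controls.

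Of 18 macrophage markers, 8 were higher in the BMDM and 0 lower (9 and 0 adjusted over the list alone; median 1.05, adjusted p = 2.9e-05 by camera, adjusted p = 0.31 with an estimated correlation). Selenop rose 6.85-fold, the F4/80 gene Adgre1 3.15-fold, Ms4a7 8.31-fold and the complement gene C1qa 14.9-fold. Each of the last 3 fell short in 5 of the 8 fits without a library (edgeR, adjusted p from 0.050 to 0.13). These were the fits without BMDM control 1, control 2 or knockout 1 for all 3, without BMDM knockout 2 for Adgre1 and C1qa, without BMDC control 1 for Ms4a7 and C1qa, and without BMDC control 2 for Adgre1 and Ms4a7. Without BMDC control 2 the list median was 1.65. C1qa stood at 2.76 and 17.3 CPM in the BMDC controls, and its log2 difference ranged from 3.13 to 5.78 over the fits without 1 library. Of 15 neutrophil and granulocyte precursor markers 7 were lower in the BMDM (13 adjusted over the list alone; median −5.23, or −4.49 with genes at 0 set at their bound against 3 counts per library; adjusted p = 5.4e-08, adjusted p = 0.28 with an estimated correlation). Over the fits without 1 library the median ranged from −6.68 to −3.45, the latter without BMDC control 2. Mmp8 stood at 1817 CPM in the BMDC against 48.6 in the BMDM, Mmp9 at 762 against 33.8, Lcn2 at 812 against 11.4 and Ly6c2 at 450 against 1.47.

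Of 15 dendritic cell markers 4 were lower in the BMDM (5 adjusted over the list alone; median −0.89, adjusted p = 0.0073, adjusted p = 0.28 with an estimated correlation), with Irf4, a transcription factor gene of this lineage, at 10.8 against 0.203 CPM and Kit at 126 against 0.977. Ccl22 had a log2 difference of −6.02 and Clec9a one of −3.64. Of 13 monocyte markers 5 were lower and 1 higher (8 and 1 adjusted over the list alone; median −2.71, adjusted p = 0.0068, adjusted p = 0.48 with an estimated correlation), with Vcan at 132 against 2.33 CPM and Spn at 9.69 against 116. Neither list passed without BMDC knockout 1 (adjusted p = 0.061 and 0.057) or knockout 2 (0.068 and 0.063). Without BMDC control 2 their medians were −0.45 and −1.48, and without BMDM control 1 that of the dendritic cell markers was −1.89. MHC class II and antigen presentation genes as a list did not pass (median −0.11, adjusted p = 0.35 by camera). In that list 2 of 23 were lower (3 adjusted over the list alone), the costimulator genes Cd86 (−3.17) and Cd80 (−1.33), while H2-Aa (−0.73) and H2-DMb2 (−2.30) were not past the threshold. Both passed without BMDC knockout 1 or 2 and in a fit of the 4 controls alone, and H2-DMb2 also with DESeq2 and with the gene-length trend removed.

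Inflammatory cytokine genes were lower in the BMDM (14 of 31 lower and 2 higher, 16 and 2 adjusted over the list alone; median −2.49, or −1.98 with genes at 0 at their bound; adjusted p = 1.2e-05, adjusted p = 0.48 with an estimated correlation). Glycolysis and hypoxia genes were lower (12 of 26 lower and 1 higher, 13 and 1 adjusted over the list alone; median −0.91, adjusted p = 4.5e-05), as were stromal and fibroblast genes (4 of 11, 9 adjusted over the list alone; median −4.23, adjusted p = 8.7e-07). Heat shock genes were higher (3 of 13, 4 adjusted over the list alone; median 0.59, adjusted p = 0.0026). Each of these 3 lists had an adjusted p = 0.28 with an estimated correlation. Leaving out 1 library in turn, the median ranged from −3.39 to −1.94 for the cytokine genes. For the stromal and fibroblast genes it ranged from −5.31 to −3.10. LXR and PPAR lipid genes (median 0.43), cell cycle genes (0.42) and mast cell markers (−3.14) passed at an adjusted p = 0.035 and were lost without BMDC knockout 1 (adjusted p = 0.086, 0.088 and 0.074) or knockout 2 (0.085 each), and with an estimated correlation (adjusted p = 0.28, 0.73 and 0.68). Cell cycle genes were also lost without BMDC control 1 (−0.09) or BMDM control 2 (0.18), and mast cell markers without BMDC control 2 (0.14), where cell cycle genes stood at 1.37 and LXR and PPAR genes at 0.78. In all, 11 of 28 lists passed, 4 higher and 7 lower, with 7 without BMDC knockout 1 or 2.

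The count of genes differing between the control cultures depended on each library, including knockouts, which share the estimate of spread. It was 4877 and 4866 without BMDC knockouts 1 and 2, 383 and 473 without BMDC controls 1 and 2, 218 and 223 without BMDM controls 1 and 2, and 582 and 574 without BMDM knockouts 1 and 2. DESeq2 called 2212, and a fit of the 4 controls alone, chosen after seeing the data, 4311.

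In the authors' deposited table for the BMDC, 1 gene, Lyz2, had an adjusted p under 0.05 (log2 fold change −6.94), and Trpv2 had a log2 fold change of −2.21 with an adjusted p of 0.40. In the authors' deposited table for the BMDM, 8 genes did, 1 higher and 7 lower, and each of the 8 was also called here.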

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

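The tests of explanations given here were all chosen after the results they bear on had been seen, as were the removal of the gene-length trend and the library quality weights.

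By camera on the BMDM minus BMDC difference, 8 gene lists passed at the preset correlation, which takes list members as nearly independent. None did with an estimated correlation (smallest adjusted p = 0.67), a test with little power here. The difference in median log2 fold change was −2.02 for interferon-stimulated genes (adjusted p = 0.024, 49 genes), with medians of 2.10 in the BMDC and 0.0033 in the BMDM. It was 1.00 without BMDC knockout 2, and the list did not pass without BMDC control 2 (−1.82) or BMDM control 1 (−1.53). For MHC class II and antigen presentation genes it was −0.87 (adjusted p = 0.0050 by camera, 23 genes), and 0.21 without BMDC knockout 2. For cell cycle genes it was −1.04 (adjusted p = 9.6e-07, 35 genes), and −0.49 without BMDC knockout 1 (adjusted p = 0.34). With the gene-length trend removed, the interferon-stimulated (−1.81), macrophage (−0.39) and B and plasma cell (−3.22) lists did not pass (each adjusted p = 0.052), nor did mast cell markers (−1.14, adjusted p = 0.074).

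Dendritic cell markers differed by −1.13 (adjusted p = 0.024, 15 genes), and did not pass without BMDC control 1, knockout 1 or knockout 2 or BMDM control 1 (adjusted p = 0.17, 0.16, 0.074 and 0.061). Macrophage markers differed by −0.82 (adjusted p = 0.025, 18 genes), lost without BMDC control 1, knockout 1 or knockout 2 or BMDM control 2 or knockout 2 (adjusted p = 0.70, 0.084, 0.14, 0.11 and 0.099). Heat shock genes differed by 0.37 (adjusted p = 0.024, 13 genes), lost without BMDC control 1 or knockout 1 or BMDM control 1, control 2 or knockout 2 (adjusted p = 0.050, 0.34, 0.058, 0.11 and 0.17). B and plasma cell markers differed by −3.21 (adjusted p = 0.029, 7 genes), lost without BMDC control 1, knockout 1 or knockout 2 or BMDM control 2 or knockout 2 (adjusted p = 0.12, 0.084, 0.33, 0.084 and 0.11). Mast cell markers differed by −1.59 (adjusted p = 0.034 by camera, 7 genes). They were lost without BMDC control 1, knockout 1 or knockout 2 or BMDM control 1, control 2 or knockout 2. In the BMDM alone, 1 mast cell marker and 4 B and plasma cell markers passed the filter, too few for a test there. All mast cell markers together came to 2.58 to 3.61 CPM in the BMDM libraries, so the BMDM side of their difference lies near the floor.

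BMDC knockout 2 stood apart from the other BMDC libraries, with interferon-stimulated genes far above them. Its gene-length trend as the source of those genes was argued against, since their median deviation was 3.21 with the trend and 3.07 (quartiles 2.21 to 4.23) with it removed, and the SD of its deviations over all genes went only from 1.06 to 0.94, against at most 0.6 in the other libraries. The marker CPM of B, T and NK cells was small beside those reads, but it is not a share of cells. It therefore cannot decide how many of those reads such cells carried. The marker CPM came to 0.46% of the gain in interferon-stimulated CPM (82 of 17965). Of the B and plasma cell markers 10 of 15 were matched, and of the T and NK cell markers 8 of 17. Marker CPM cannot show whether a few such cells induced the list in the other cells. The genotype alone, raising the list alike in each knockout culture, was argued against by knockout 1, where the median deviation was −0.9 (quartiles −1.4 to −0.63). An interferon response in that culture or mouse, or a genotype effect that shows in part of the mice, may remain, and neither was tested.

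Lyz1 fell with Lyz2 in the BMDM, where Lyz2 reads counted to Lyz1 could account for 10% of the Lyz1 reads lost by BMDC control 1, with 17 Lyz1 reads beside 322346 of Lyz2, and for 13.5% by control 2, with 33 beside 405796. Both use the upper 95% limit of the ratio and assume the same share of shared reads in both cell types. A fall of all genes around Lyz2 was argued against by the median of the 10 other listed neighbours, 0.05 (quartiles −0.06 to 0.09). The residual Lyz2 level of the 4 knockout libraries was at most 0.83% of control relative to library totals and 1.08% with TMM scaling, consistent with a Lyz2 locus altered on both alleles. An effect of the Cre insertion on Lyz1 in particular may remain and was not tested.

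Besides Trpv2, Lyz2 and Lyz1, 9 genes were called in the BMDM. A gene-length trend between the libraries was argued against, since 9 of the 9 were still called with it removed. A difference in genetic background between the control and Cre-carrying mice cannot be told apart from an effect of Trpv2 loss. The same holds for Cre itself and for the low Lyz2, which went with Trpv2 loss in each knockout library. Each of these allows the same direction in the BMDC, seen for 5 of the 7 genes tested there (exact two-sided binomial p = 0.45). No library carried Cre without the loxP-flanked alleles.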

How the results depend on the processing

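The quality weights, the removal of the gene-length trend, the crossed block and the fit of the 4 controls were chosen after the results had been seen. Over the alternatives that keep all libraries, the named genes other than Trpv2 and Lyz2 kept their direction and their side of the threshold in 436 values for the BMDC, 385 for the BMDM and 199 for the cell types. In the BMDC 5 of their values newly passed, Ms4a14 and Ccl17 with DESeq2 and these and Rnase4 with the gene-length trend removed and a replicate block. In the BMDM 6 newly passed (Il1a in 4, Il1b and Axl with the crossed block) and 24 no longer did, and between cell types 4 (H2-DMb2 in 3, H2-Aa in 1) and 1. The cause was not tested. With a lone library in a group its spread is assumed to equal that of the others. The simulations had 2 libraries in each group and the same spread in all of them. There, edgeR recovered 0 of 100 simulated 2-fold changes at the BMDC spread and 93 of 100 at that of the BMDM. They cover neither changes in genes of low count, nor a lone library, nor a library that stands apart, as BMDC knockout 2 did.

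In the BMDC, 1 gene passed without the low-count filter, 6 with DESeq2, 1 with quality weights, 18 with the gene-length trend removed and a replicate block, and 1 in the joint fit. Calls shared by both cell types numbered 1, 3, 1, 3 and 1 under these, where independent lists would share at most 0.0065. Lyz2, the Cre locus, was among them each time, and Trpv2 where there were 3, so part of this overlap was fixed by the design. BMDC Lyz2 then passed at −6.95, −6.92, −6.98, −7.34 and −6.93, and Trpv2 with DESeq2 (−2.19) and with the trend removed and the block (−2.21). The joint fit called 2 genes in the BMDM, DESeq2 2212 and the 4 controls alone 4311 between cell types. With an estimated correlation 0 lists passed in the BMDC, 0 for the difference and 0 between cell types. With the trend removed 3 lists passed in the BMDM and 4 for the difference, where Lrmda turned to 0.12, and with the 4 controls alone 7 between cell types. The cause was not tested.

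Replicate numbers are shared between groups and nothing says what they mark; deviations of same-numbered libraries correlated at −0.0016 in the BMDC and −0.24 in the BMDM over genes. With a replicate block 2 genes passed in the BMDC (Lyz2 at −7.00), 1 was shared by both cell types, and 2 lists passed in the BMDM, where the cell cycle list had a median of −0.0069 with its test turned down. The BMDC heat shock list (−0.32, adjusted p = 0.072), Colec12 in the BMDM (0.79, adjusted p = 0.20) and Ccn3 between cell types (adjusted p = 0.086) no longer passed. Crossed pairing called 29 genes in the BMDM, 21 higher and 8 lower.

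Leaving out each library in turn gave 0 to 3215 genes in the BMDC, 11 to 34 in the BMDM, 0 to 3733 for the difference, 218 to 4877 between cell types and 0 to 5 shared, and 3 to 13, 0 to 9, 2 to 11 and 7 to 14 lists. Of the named genes other than Trpv2 and Lyz2, 26 newly passed in at least 1 of these fits in the BMDC, and in the BMDM Rsad2, Il1a and Il1b did. Trpv2 ranged from −2.55 to −1.93 in the BMDC and from −3.39 to −3.23 in the BMDM, Lyz2 from −7.47 to −6.55 and from −7.95 to −7.72. Results whose test turned direction in the BMDC were the lists of mast cell markers (−0.16 to 4.60), MHC class II (−0.12 to 1.41), mitochondrial transcripts (−0.10 to 1.15) and interferon-stimulated genes (−0.95 to 2.99), and Ifi27l2a (−0.98 to 5.71), Ifi205 (−0.58 to 5.45), Ifi44 (−0.95 to 5.44), Hdc (−0.16 to 2.66), Cd79a (−0.052 to 4.39) and Frs2 (−1.61 to 0.048). The median crossed 0 with the test unturned for B and plasma cell markers (−0.052 to 3.48), phagocytosis (−8.1e-04 to 0.58) and the genes around Lyz2 (−0.65 to 0.021). In the BMDM they were cell cycle (−0.12 to 0.062), cytokines (−0.23 to 0.74), MHC class II (−0.11 to 0.15) and interferon-stimulated genes (−0.28 to 0.47), and Rsad2 (−0.027 to 0.99), Tap2 (−0.35 to 0.046) and Frs2 (−0.13 to 0.56), and the median alone crossed 0 for calcium entry (−0.047 to 0.031), the genes around Lyz2 (−0.082 to 0.13) and phagocytosis (−0.048 to 0.14). For the difference they were MHC class II (−1.38 to 0.21), interferon-stimulated genes (−2.90 to 1.00) and Lrmda (−0.94 to 0.46). Between cell types the median alone crossed 0 for cell cycle (−0.086 to 1.37) and mast cell markers (−4.65 to 0.14).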

Other observations

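The genes named in this part were chosen after their values were seen, and no test was made of them here. Ifnb1, which encodes interferon beta, had 7 and 0 reads in the BMDC controls, 1 in knockout 1 and 133 in knockout 2, the library with high interferon-stimulated genes. In the BMDM it had 6 and 1 reads in the controls and 0 and 2 in the knockouts. The interferon-stimulated genes together made up 4738 and 3382 CPM in the BMDC controls, 2464 in knockout 1 and 21493 in knockout 2. In the BMDM they made up 6843 and 4631 CPM in the controls and 6037 and 7007 in the knockouts.

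Eif2s3y, which fell in the BMDM knockouts, had 996 and 1006 reads in the controls and 599 and 427 in the knockouts. The other Y-linked genes of the BMDM did not share this: Ddx3y had 548 and 652 against 869 and 529 reads, Uty 172 and 266 against 374 and 226, and Kdm5d 171 and 328 against 334 and 275. In the BMDC all 4 were lowest in knockout 2. Eif2s3y had 437 reads there (951 to 1231 in the other libraries) and Ddx3y 503 (744 to 1411). Uty had 80 (251 to 359) and Kdm5d 174 (458 to 498). These reads are unscaled, and the level of knockout 2 also followed gene length. TMM-scaled, Eif2s3y stood at 30.8 CPM in knockout 2 and from 47.0 to 64.3 CPM in the other BMDC libraries. Gm15446, the called gene with a predicted name, had 33 and 55 reads in the BMDM controls and 2 and 1 in the knockouts, a ratio of 3.29% (95% interval 0.666% to 9.94%), and 97 and 56 against 1 and 3 reads in the BMDC (2.74%, 0.737% to 7.16%). Neutrophil and granulocyte precursor markers together made up from 4319 to 5822 CPM in the BMDC libraries and from 181 to 207 CPM in the BMDM libraries.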
